A study of Caenorhabditis elegans with 8 samples.

How the data were processed

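Gene counts came from 8 RNA sequencing libraries of whole Caenorhabditis elegans, 4 of strain N2 and 4 of strain HBR227 with genotype aptf-1(gk794). Per the labels' protocols, eggs were obtained by hypochlorite treatment, kept in M9 buffer, and collected as arrested L1 larvae after 48 hours; RNA was isolated with Trizol after bead beating and libraries followed Illumina protocols. The deposited table holds raw counts per gene, not scaled, for all 8 libraries. Bowtie 0.12.2 and the genome builds WBcel235 and mm8 are named in the submitters' processing notes without a role, and WBcel235 is the worm build. The counting program, the annotation release, the filters and whether strand was used in counting are not given in the sources used here. Where strand was not used, reads from a gene and an overlapping gene on the other strand cannot be told apart, so overlaps with exons of other genes are stated for named genes in which they are large. How reads mapping to several copies were counted is not given either, so members of near-identical gene pairs are reported as uncertain.

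The table had 46433 rows. In 11 rows the gene name had been turned into a date, and these rows, with 0.0334% of all counts and at most 0.0357% of any library, were left out of library sizes and tests. In 471 rows several gene names were joined. In 18253 rows every library had 0 counts. Row names were matched to Ensembl release 115 gene models of WBcel235, directly by symbol for 41633 names, through the coordinates of RefSeq symbols for 3328 and through RefSeq synonyms for 732. In all, 729 names stayed unmatched, and 133 of the genes tested had no coordinates. Coordinates are 1-based.

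Counts were tested in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM, genes were kept by filterByExpr with its default minimum count of 10, and HBR227 was compared with N2 by the quasi-likelihood F test with robust estimation over all 8 libraries and no covariate. P-values were adjusted by the Benjamini-Hochberg method over the 17522 genes tested, and adjusted p under 0.05 was called. Log2 fold changes are HBR227 minus N2, and each standard error was derived from the fold change and its F statistic. CPM values are TMM-scaled. The labels call the libraries biological replicates but do not say which came from separate cultures, so p-values measure the spread between these samples. The common biological coefficient of variation was 0.152.

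The groups, the tests, the processing alternatives, 49 gene lists and the rule for named genes were fixed before the data were examined. The rule names aptf-1 and flp-11, then the 10 genes with the largest rise and the 10 with the largest fall among genes with an adjusted p under 0.05, an average log2 CPM of at least 1 and all 4 values of one strain above all 4 of the other, then up to 4 called members with the smallest p from each list. Other genes are named as chosen after their values were seen. Lists were drawn from gene name families and general knowledge of the worm, some genes are on more than 1 list, and called members were counted over all genes and over the list alone. Lists with at least 5 tested members, which all 49 had, were also tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and with a correlation estimated per list, and with fry, and adjusted over lists. Features of the libraries were compared by exact two-sided permutation tests.

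Each alternative replaced 1 choice: DESeq2 size factors, upper quartile scaling or total counts alone; limma voom as the test, or DESeq2 1.42.0 with its own scaling and filter, which therefore changed these too (28169 genes entered); no low-count filter, or a CPM of at least 1 in 4 libraries; an adjusted p under 0.01; a test against a fold change of 1.5; the replicate letter as a block; and each library left out in turn. The 35 ways to split the 8 libraries into 4 and 4 were each refitted. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

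The scripts were tested on simulated counts for this comparison, drawn for 17522 genes from the real means and library sizes, with 100 genes changed 1.5-fold and 100 changed 2-fold. Of the changed genes 42.0% were recovered at 1.5-fold and 70.4% at 2-fold, 0 with the wrong sign, 5.93% of the calls were unchanged genes, and 0 of 100 random lists of unchanged genes were called. A change of 1.5-fold in a single gene was thus often missed in this simulation. Each gene was drawn independently, so the random lists could not show how the list test behaves where the genes of a list vary together. Only 200 genes were changed there, against 3774 called in the real data, where 63.4% of the calls were under 1.5-fold. The Benjamini-Hochberg cut is stricter where fewer genes change, so these recoveries do not give the sensitivity of the real comparison.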

Results

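Whole Caenorhabditis elegans larvae held in L1 arrest for 48 hours were compared between 2 strains by RNA sequencing. L1 arrest is the state of larvae that hatch without food and stop developing. The wild-type strain N2 and the mutant strain HBR227, which carries the gk794 allele of aptf-1, were each represented by 4 libraries that the labels call biological replicates A to D. The gene aptf-1 encodes an AP2 transcription factor needed by RIS, a neuron whose activity brings on sleep, and for expression of flp-11, the neuropeptide gene through which RIS acts. The comparison asks which transcripts differ in arrested larvae that lack this factor. Total counts in M (mega-counts) were 43.6, 56.4, 47.8 and 52.4 in N2 replicates A, B, C and D, and 48.4, 65, 53.5 and 52 in HBR227 replicates A, B, C and D. Mean depth was 50 ± 5.58 M in N2 and 54.7 ± 7.17 M in HBR227 (SD, n = 4 each; exact two-sided permutation p = 0.343, where 0.0286 is the smallest p this design allows).

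The libraries separated by strain, but HBR227 replicate A lay apart from the other 7. The first principal component of log2 CPM held 46% of the variance and placed HBR227 A at 74.3, with the other libraries between -28.3 and 9.86. The second held 28.7% and placed HBR227 B, C and D at -33.9 to -26.1 and the N2 libraries at 13.3 to 23.5, with HBR227 A at 27.4. Across genes, which are not independent replicates, the Pearson correlation of HBR227 A with the other HBR227 libraries was 0.972 to 0.973, against at least 0.994 among HBR227 B, C and D and 0.993 to 0.994 among the N2 libraries. Mitochondrially encoded genes took 0.633% ± 0.0441 of the counts in N2 and 0.523% ± 0.101 in HBR227 (SD, n = 4 each; exact permutation p = 0.0571, 0.171 adjusted over 6 library features), with HBR227 A at 0.377%. No pair of libraries was a repeat of the other, since chi-square per degree of freedom was 4.68 or more in every pair of the same strain.

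**Figure D1:**
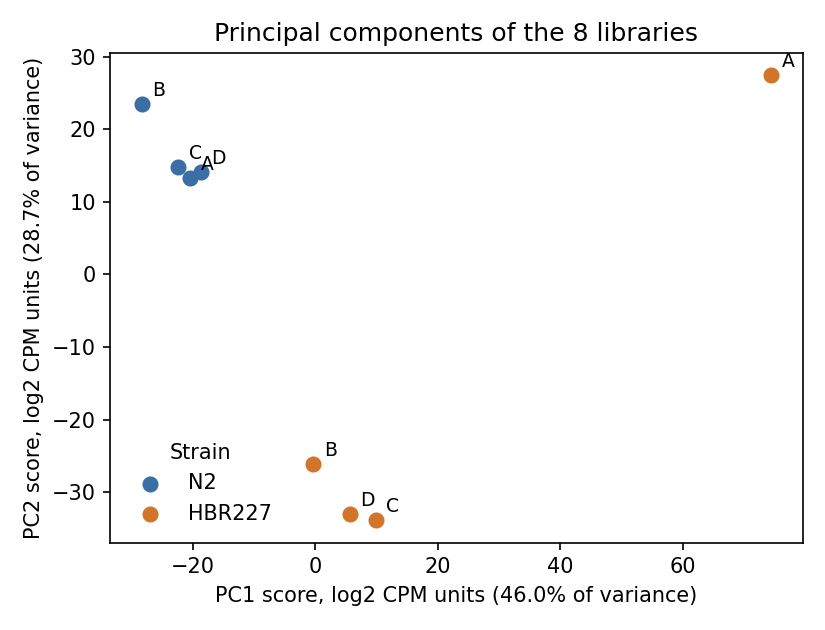
Scores of the 8 libraries on the first (x axis, 46% of variance) and second (y axis, 28.7% of variance) principal components of log2 CPM, with 1 point per library, coloured by strain and lettered by replicate. HBR227 A sits at 74.3 on the first axis, and HBR227 B, C and D sit at -33.9 to -26.1 on the second, under all N2 libraries.

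Transcripts of the mutated gene were lower in every HBR227 library than in any N2 library. aptf-1 (WBGene00019424, chromosome II, 6454971 to 6456546, plus strand, WBcel235; protein-coding) had 161, 196, 182 and 234 counts in N2 A to D and 33, 69, 56 and 52 in HBR227 A to D. Its TMM-scaled CPM was 3.73 ± 0.463 in N2 and 0.982 ± 0.176 in HBR227 (SD, n = 4 each), a log2 fold change of -1.92 ± 0.16 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.1e-04). Gene-level counts do not show which part of the gene the remaining reads came from, and 2.90% of its exon length overlaps exons of dgk-5 on the opposite strand. flp-11 (WBGene00001454, chromosome X, 4677334 to 4678129, minus strand; protein-coding) had the smallest adjusted p of all genes tested. Its CPM was 152.7 ± 8.18 in N2 and 44.9 ± 1.87 in HBR227 (SD, n = 4 each), a log2 fold change of -1.77 ± 0.06 (adjusted p = 5.7e-07). The aptf-1 and flp-11 levels of HBR227 A, at 0.720 and 46.4 CPM, lay below all N2 libraries, so its label was used as given.

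Differences between the strains were many and mostly small. Of 17522 genes tested, 3774 passed an adjusted p of 0.05 (21.5%), with 1960 higher and 1814 lower in HBR227. Only 128 of the higher and 311 of the lower genes changed at least 2-fold, and 63.4% of the calls were under 1.5-fold. The 8 libraries separated fully by strain at 28.9% of the genes, against 2.86% by chance. Without HBR227 A the calls rose to 7906 (3748 higher, 4158 lower), and 3760 of the 3774 genes were called again in the same direction. With total counts alone as the scale, the split became 1174 higher and 3111 lower (27.4% higher, against 51.9% with TMM), and the median log2 fold change of all genes moved to -0.11. The TMM factors themselves separated the strains, at 1.02 to 1.07 in N2 and 0.946 to 0.985 in HBR227 (exact permutation p = 0.0286, 0.171 adjusted over library features). With DESeq2 size factors 53.7% of the calls were higher, and with upper quartile scaling 52.4%. The near-even split of directions was thus seen with these scalings and TMM, but not with total counts alone.

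Among genes with an average log2 CPM of at least 1 and full separation of the libraries, the largest rises were led by ZK218.1 (chromosome V, 17092562 to 17093546), from 2.86 ± 0.528 to 15.7 ± 2.18 CPM (SD, n = 4; log2 fold change 2.46 ± 0.16, adjusted p = 3.9e-05). The small heat shock protein genes hsp-16.49 (2.03 ± 0.26) and hsp-16.48 (1.91 ± 0.24) followed, on chromosome V at 9089280 to 9089766 and 9088131 to 9088617. Next came the aspartyl protease gene asp-16 (1.61 ± 0.14), the collagen gene col-106 (1.61 ± 0.22), F10A3.4 (1.5 ± 0.22), nspc-18 (1.44 ± 0.15), the F-box gene fbxa-136 (1.41 ± 0.22), the lysosomal lipase gene lipl-3 (1.38 ± 0.27) and the C-type lectin gene clec-54 (1.36 ± 0.25). The largest falls were in D1086.3 (-2.57 ± 0.35), lmd-4 (-2.54 ± 0.13), which encodes a LysM domain protein, D1086.9 (-2.50 ± 0.34), F14F9.2 (-2.46 ± 0.18) and ZK354.3 (-2.23 ± 0.17). D1086.3 and D1086.9 lie near each other on chromosome V, starting at 14092792 and 14104270. In N2, lmd-4 stood at 12.1 ± 1.33 CPM, and in HBR227 at 2.08 ± 0.240 (adjusted p = 8.6e-06). After aptf-1, the list continued with F32A7.8 (-1.81 ± 0.10), flp-11, W03F9.4 (-1.74 ± 0.22) and clec-180 (-1.70 ± 0.14), the last of which went from 46.1 ± 4.66 to 14.1 ± 2.95 CPM (SD, n = 4).

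**Figure D2:**
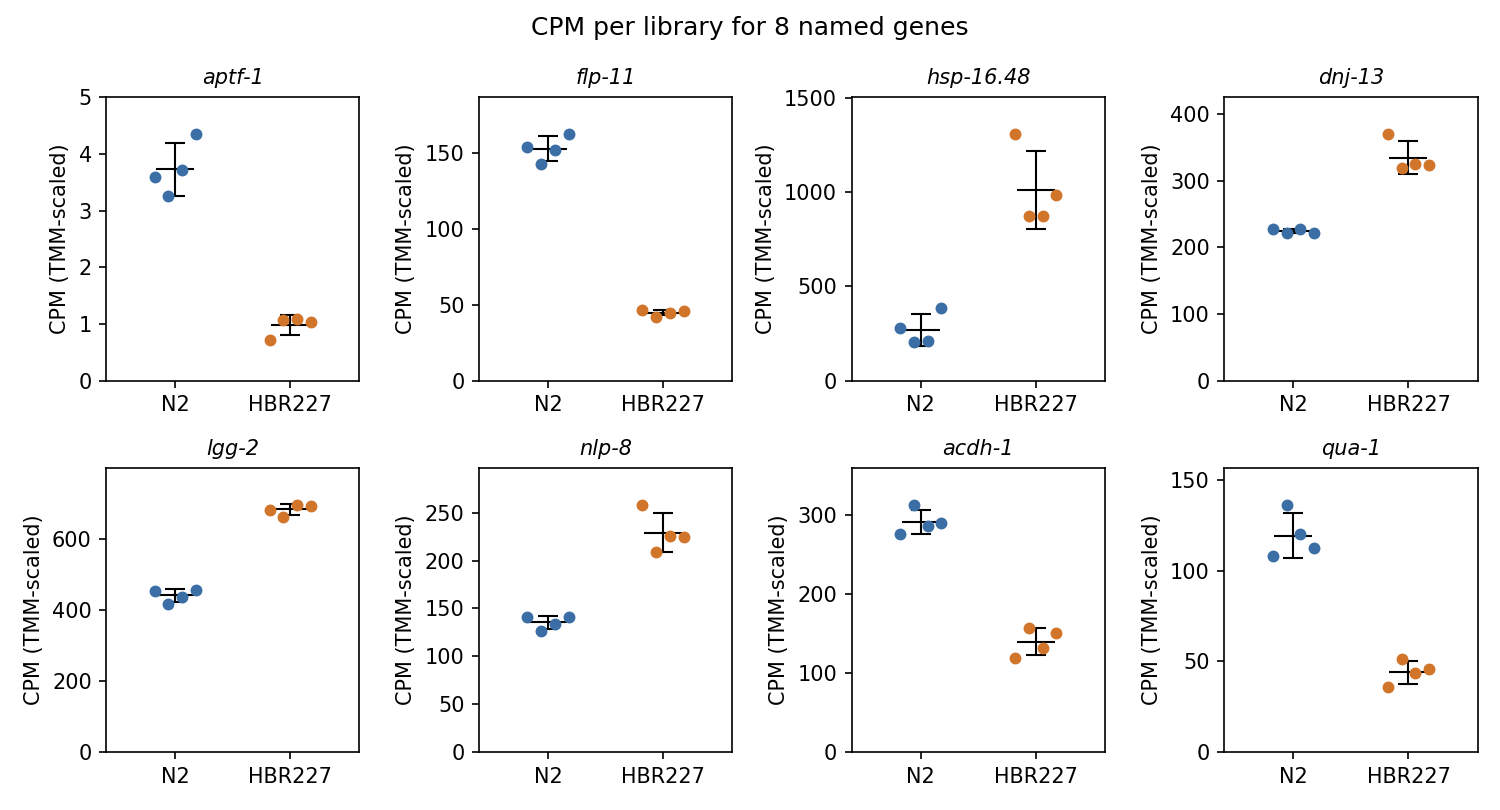
TMM-scaled CPM (y axes, linear, from 0) of 8 genes in the 4 N2 and 4 HBR227 libraries (x axes); points are libraries, and the black bar and whiskers are the mean and SD of 4. Mean flp-11 was 152.7 CPM in N2 and 44.9 in HBR227, mean hsp-16.48 was 270 and 1011, and the 2 strains did not overlap in any of the 8 genes.

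Most genes of the heat shock list were higher in the mutant. Of 18 heat shock genes tested, 15 rose, none fell and 3 did not pass the test, with the same counts adjusted over the list alone and without HBR227 A. The J-domain genes dnj-13 (225 ± 3.51 to 335 ± 24.1 CPM, SD, n = 4; log2 fold change 0.58 ± 0.06, adjusted p = 2.0e-04) and dnj-12 (0.41 ± 0.04) rose, as did the small heat shock genes hsp-16.11 (0.61 ± 0.06) and hsp-16.1 (0.64 ± 0.06). Chosen after their values were seen, the major chaperones hsp-90 (0.33 ± 0.06), hsp-1 (0.36 ± 0.07) and hsp-110 (0.34 ± 0.10) also rose, and the 3 members that did not pass were hsp-70 (0.19 ± 0.09), stip-1 (0.04 ± 0.07) and hsp-17 (-0.04 ± 0.13). Outside the list, the small heat shock gene hsp-12.3, also named after its value was seen, fell (-0.65 ± 0.19). The pairs hsp-16.1 and hsp-16.11, hsp-16.48 and hsp-16.49, and F44E5.4 and F44E5.5 are near-identical copies that can share reads, so their separate values are uncertain. F44E5.4 and F44E5.5 had almost equal means of 8908 and 8926 CPM in N2 and 12013 and 12036 in HBR227. The list median was 0.43, and camera gave adjusted p = 1.3e-11 with a preset correlation and adjusted p = 0.191 with an estimated correlation. For all 49 lists together, camera with the preset correlation called 16 (10 higher, 6 lower). However, every other split of the libraries into 4 and 4 called 16 to 34. No list was called with an estimated correlation (2 at an unadjusted p under 0.05), so member counts lead in what follows. With fry, 11 lists were called, and heat shock genes had the smallest adjusted p (1.3e-04). Over all 17522 genes tested, 1960 were higher and 1814 lower (21.5% called), and list counts need to be read against these shares. In the fit without HBR227 A, 7906 of 17850 genes tested were called (3748 higher, 4158 lower). List counts from that fit need to be read against this larger share. The low-count filter was rerun there, so the number of tested members of a list can differ.

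Many neuropeptide genes rose, while flp-11 fell. Of 63 NLP neuropeptide genes, 28 rose and none fell (33 and 2 adjusted over the list alone), with a median log2 fold change of 0.23. The 2 lower over the list alone were nlp-22 (-1.70 ± 0.61) and nlp-63 (-0.64 ± 0.22), named after their values were seen. Examples of the rises were nlp-64 (0.79 ± 0.06), nlp-8 (135 ± 7.07 to 229 ± 20.8 CPM, SD, n = 4; 0.76 ± 0.07), nlp-2 (0.73 ± 0.08) and nlp-9 (0.59 ± 0.06). Of 30 FLP neuropeptide genes, 15 rose and only flp-11 fell (21 and 2 adjusted over the list alone), with a median of 0.25. The other gene lower over the list alone was flp-3 (-0.15 ± 0.06), named after its value was seen. Among the rises, flp-10 rose from 24.9 to 52 CPM (1.06 ± 0.11), and flp-12 and flp-18 both rose by 0.41 ± 0.06. Camera gave adjusted p = 9.0e-08 for NLP and adjusted p = 1.3e-06 for FLP genes, and adjusted p = 0.566 and adjusted p = 0.600 with an estimated correlation. Without HBR227 A, 38 of 64 tested NLP genes were higher and 4 lower. Of 30 FLP genes 24 were then higher and 2 lower, and of 20 pan-neuronal genes 12 were higher and 0 lower. Genes of the pan-neuronal list showed smaller shifts, with 7 of 20 higher and none lower, also adjusted over the list alone. Among them were ida-1 (0.34 ± 0.05), rpm-1 (0.32 ± 0.07), egl-21 (0.27 ± 0.06) and sbt-1 (0.24 ± 0.05), which act in dense-core vesicles, peptide processing or synapse formation. The pan-neuronal median was 0.09 and turned to -0.01 with total counts alone (camera adjusted p = 0.0028, and adjusted p = 0.695 with an estimated correlation).

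Sleep genes were split, with several rises beside the fall of flp-11. Among 17 sleep signalling genes, 7 rose and only flp-11 fell (11 and 2 adjusted over the list alone), with nlp-8, nlp-14 (0.46 ± 0.08) and npr-22 (0.57 ± 0.09), a neuropeptide receptor gene, leading the rises. The sleep peptide gene nlp-22, at 0.479 ± 0.181 CPM in N2 and 0.140 ± 0.130 in HBR227 (SD, n = 4; adjusted p = 0.074), was lower over the list alone and was called without HBR227 A (adjusted p = 0.019). The list median was 0.17 and the mean 0.03 (camera adjusted p = 0.013, and adjusted p = 0.603 with an estimated correlation). Of 13 genes used by RIS or for GABA signalling, the neuropeptide receptor gene dmsr-1 (0.25 ± 0.06) and the GABA receptor gene unc-49 (0.34 ± 0.10) rose. From the same list flp-11 fell and 10 did not pass the test, with the same counts adjusted over the list alone. The values of lim-6 (-0.27 ± 0.16), unc-25 (-0.08 ± 0.12) and unc-47 (0.10 ± 0.14), named after their values were seen, were among those 10. Insulin-like peptide genes went both ways, with 7 of 26 higher and 5 lower (7 and 6 adjusted over the list alone). The rises included daf-28 (0.77 ± 0.14) and ins-3 (0.71 ± 0.12). The falls were ins-24 (-0.61 ± 0.08), ins-35 (-0.58 ± 0.12), ins-20 (-0.72 ± 0.18), ins-37 (-1.37 ± 0.35) and ins-2 (-0.52 ± 0.16), the last 3 named after their values were seen. Other genes overlap 20.1% of the ins-37 exon length on the opposite strand and 17.9% on its own, so its value is uncertain. The insulin median was 0.00 and the mean -0.01, and the median turned to -0.10 with total counts alone. Higher and lower counts without HBR227 A were 11 and 2 for sleep, 3 and 1 for RIS and GABA and 7 and 7 for insulin genes.

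Chemoreceptor and cilium genes were called less often than the 21.5% of all genes tested, and 4 of 10 glia markers fell. Chemoreceptor genes had 30 of 460 tested members higher and 14 lower (14 and 5 adjusted over the list alone), with srg-25 (2.42 ± 0.25), srh-75 (2.05 ± 0.25), str-112 (1.29 ± 0.16) and srw-86 (0.72 ± 0.09) as the most clearly called. Of these, srg-25 and srh-75 stayed near 1 CPM in HBR227, at 1.02 and 1.23. The chemoreceptor median was 0.12, with 273 members above 0 and 187 below (camera adjusted p = 0.133, and adjusted p = 0.893 with an estimated correlation). The whole family held only 0.0676% of the counts in N2, so few calls do not show that it was unchanged. Of 37 cilium genes, 4 fell and none rose, also adjusted over the list alone: che-10 (-0.47 ± 0.08), dyf-11 (-0.60 ± 0.13), kap-1 (-0.39 ± 0.09) and mksr-2 (-0.65 ± 0.16). Among 10 glia markers, 4 fell and none rose, also adjusted over the list alone: vap-1 (59.9 ± 3.98 to 38.9 ± 6.63 CPM, SD, n = 4; -0.62 ± 0.12), grl-2 (-0.80 ± 0.17), delm-2 (-1 ± 0.24) and mls-2 (-0.40 ± 0.11). The glia median was -0.36 (camera adjusted p = 0.023, and adjusted p = 0.566 with an estimated correlation), and the list was not called without HBR227 A (median -0.29, adjusted p = 0.26). Higher and lower counts without HBR227 A were 59 and 25 for chemoreceptor genes, of 518 tested there, 2 and 5 for cilium and 1 and 4 for glia genes.

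Autophagy genes and nuclear hormone receptor genes rose in part. Of 28 autophagy genes, 13 rose and none fell (14 and 2 adjusted over the list alone), with the ATG8 homologue lgg-2 (440 ± 18.5 to 682 ± 15.5 CPM, SD, n = 4; 0.63 ± 0.05), epg-9 (0.60 ± 0.05), atg-2 (0.37 ± 0.05) and atg-18 (0.36 ± 0.04) as examples. The autophagy median was 0.14 (camera adjusted p = 9.1e-04, and adjusted p = 0.223 with an estimated correlation). Of 231 nuclear hormone receptor genes, 48 rose and 12 fell (56 and 15 adjusted over the list alone). Examples were nhr-87 (0.64 ± 0.05), nhr-88 (0.60 ± 0.05), nhr-119 (0.55 ± 0.05) and nhr-120 (0.55 ± 0.06), all higher. Their median was 0.13 (camera adjusted p = 0.0035, and adjusted p = 0.695 with an estimated correlation). Without HBR227 A, 17 autophagy genes were higher and 5 lower, and 83 nuclear hormone receptor genes higher and 25 lower. Proteasome genes had 5 of 33 members higher and none lower (3 and 0 adjusted over the list alone). These were rpn-3 (0.29 ± 0.05), rpn-6.1 (0.26 ± 0.06), rpn-13 (0.27 ± 0.07), rpn-2 (0.15 ± 0.05) and, named after its value was seen, pas-1 (0.33 ± 0.10). The proteasome median was 0.13 (camera adjusted p = 0.013, and adjusted p = 0.893 with an estimated correlation) and 0.02 without HBR227 A, where 8 members were higher and 3 lower and the list was not called (adjusted p = 0.39).

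Nuclear genes of the respiratory chain and of fatty acid oxidation fell in part. Of 50 nuclear respiratory chain genes, 17 fell and 1 rose (22 and 4 adjusted over the list alone). The falls included hpo-18 (-0.59 ± 0.08), ucr-11 (-0.34 ± 0.06), cox-6B (-0.29 ± 0.04) and cyc-2.1, a cytochrome c gene (-0.26 ± 0.04). The rise was isp-1 (0.17 ± 0.05), named after its value was seen. The median was -0.14 (camera adjusted p = 3.7e-05, and adjusted p = 0.566 with an estimated correlation). Of 40 fatty acid oxidation genes, 8 fell and none rose (9 and 0 adjusted over the list alone). The acyl-CoA dehydrogenase gene acdh-1 went from 292 ± 15.6 to 140 ± 17.2 CPM (SD, n = 4; -1.06 ± 0.09, adjusted p = 8.9e-05). The genes ech-6 (-0.57 ± 0.06), acox-1.6 (-0.36 ± 0.07) and acaa-2 (-0.33 ± 0.05) fell too. Their median was -0.18 (camera adjusted p = 9.0e-04, and adjusted p = 0.566 with an estimated correlation). Without HBR227 A, 4 respiratory chain genes were higher and 35 lower, and 4 fatty acid oxidation genes higher and 17 lower. Mitochondrially encoded genes had no called member among 12 in edgeR, over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05), with a median of -0.25. Without HBR227 A their median was -0.05, with 1 higher and 3 lower. The desaturase and elongase list, which also holds acl genes, had 8 of 33 members higher and 3 lower, also adjusted over the list alone. Higher members included acl-14 (0.39 ± 0.05), acl-9 (0.38 ± 0.08), elo-1 (0.41 ± 0.07) and fat-6 (0.37 ± 0.07). Glycolysis genes had 5 of 19 higher and 1 lower, also adjusted over the list alone. The genes gpd-3 (0.31 ± 0.05), gpd-2 (0.30 ± 0.05), aldo-1 (0.24 ± 0.06), pyk-1 (0.18 ± 0.05) and pfk-1.2 (0.30 ± 0.08) rose and pgk-1 (-0.16 ± 0.05) fell, the last 2 named after their values were seen. Since gpd-2 and gpd-3 lie side by side on chromosome X and could share reads, their separate values are uncertain. The desaturase and glycolysis medians turned from 0.05 and 0.04 to -0.05 and -0.06 with total counts alone. Without HBR227 A, 15 members of the desaturase and elongase list were higher and 8 lower, and 6 glycolysis genes higher and 5 lower. Lipase genes had 3 of 21 higher and 4 lower, also adjusted over the list alone, with lipl-3 and the fat lipase gene atgl-1 (0.35 ± 0.05) higher and lips-6 (-1.37 ± 0.33) lower. The trehalase gene tre-5 (0.96 ± 0.08) was the only called gene of 14 in the glyoxylate, gluconeogenesis and trehalose list, also adjusted over the list alone. That list had a mean of 0.06 and a median of -0.00 that turned to 0.01 with DESeq2 size factors and to 0.00 with upper quartile scaling. Without HBR227 A, 4 of its genes were higher and 3 lower, and 7 lipase genes were higher and 10 lower.

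Genes induced by DAF-16, the FOXO factor of starved larvae, went both ways. Of 19 genes on a list drawn up from general knowledge, 2 rose and 5 fell (4 and 6 adjusted over the list alone), with a median of -0.15. The metallothionein gene mtl-1 fell from 43.2 ± 1.90 to 19.6 ± 4.08 CPM (SD, n = 4; -1.14 ± 0.13, adjusted p = 4.1e-04), as did nnt-1 (-0.47 ± 0.08) and, named after their values were seen, dod-3 (-0.41 ± 0.08), the superoxide dismutase gene sod-3 (-0.77 ± 0.20) and hsp-12.3 (-0.65 ± 0.19). The 2 that rose were gpd-2 and gpd-3, which lie side by side on chromosome X and changed almost equally (0.30 and 0.31). They could share reads, so their separate values are uncertain. The value of hsp-12.6, also named after it was seen, was -0.98 ± 0.33 (adjusted p = 0.067), and without HBR227 A it was called at -1.45 (adjusted p = 7.8e-09). Without HBR227 A, 5 genes of the list were higher and 8 lower, and the median was -0.01. Of 6 DAF-16 repressed dod genes, dod-22 (-0.90 ± 0.15) fell and none rose, also adjusted over the list alone. The mitochondrial stress list of 10 genes split, with hsp-6 (0.41 ± 0.05) and atfs-1 (0.33 ± 0.06) higher and dnj-10 (-0.30 ± 0.06), spg-7 (-0.26 ± 0.06) and hsp-60 (-0.29 ± 0.08, named after its value was seen) lower (3 and 4 adjusted over the list alone). Of 17 genes on a list of endoplasmic reticulum chaperones and related genes, pek-1 (0.48 ± 0.06), which is not itself a chaperone gene, hsp-4 (0.39 ± 0.09), cnx-1 (0.23 ± 0.06) and pdi-1 (0.22 ± 0.06) rose. The gene ero-1 (-0.21 ± 0.06, named after its value was seen) fell (5 higher and 1 lower adjusted over the list alone). Their median turned from 0.02 to -0.09 with total counts alone and to -0.11 without HBR227 A, where 6 were higher and 8 lower.

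**Figure D3:**
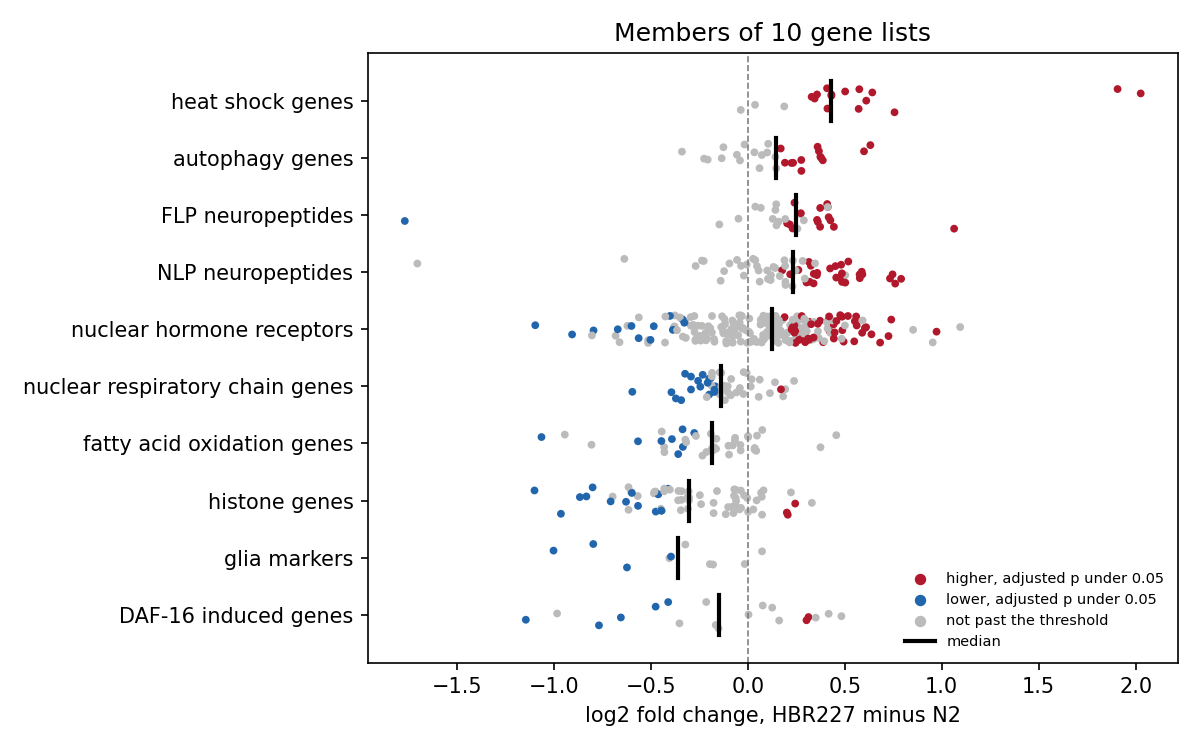
Log2 fold changes (x axis, HBR227 minus N2) of the tested members of 10 gene lists (y axis); each point is a gene, red or blue where it passed an adjusted p of 0.05 as higher or lower and grey where it did not, and black bars are list medians. Of 18 heat shock genes 15 are red, of 40 fatty acid oxidation genes 8 are blue and none red, and flp-11 lies at -1.77 among FLP genes that are otherwise grey or red.

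Moulting, histone and F-box lists held more falls than rises, and so did collagens only with HBR227 A included. Of 156 cuticle collagen genes, 24 fell and 10 rose, also adjusted over the list alone. The genes dpy-14 (359 to 192 CPM; -0.90 ± 0.09) and col-98 (-0.37 ± 0.05) fell, and col-181 (1.1 ± 0.13) and col-153 (0.99 ± 0.09) rose. Without HBR227 A, which lay 0.45 below the other HBR227 libraries in this list, 35 collagen genes were higher and 34 lower. Among 20 moulting genes, the hedgehog-related gene qua-1 fell to 44.1 ± 6.34 CPM in HBR227 (SD, n = 4; -1.44 ± 0.11, adjusted p = 8.2e-05). The genes mlt-9 (-0.67 ± 0.13) and mlt-8 (-0.51 ± 0.15) fell, and nekl-2 (0.41 ± 0.10) and nekl-3 (0.33 ± 0.10, named after its value was seen) rose (2 higher and 4 lower adjusted over the list alone). Histone genes had 14 of 69 members lower and 3 higher (18 and 3 adjusted over the list alone), with his-43 (-0.83 ± 0.14) and his-12 (-0.87 ± 0.16) lower, at means of 1.86 and 1.40 CPM in HBR227, and the variant histone gene his-71 (0.24 ± 0.04) higher. Many histone genes are near-identical copies, so single members are uncertain. Their median was -0.30 (camera adjusted p = 7.1e-04, and adjusted p = 0.566 with an estimated correlation). F-box and MATH genes had 76 of 403 members lower and 18 higher (79 and 22 adjusted over the list alone). Among them were fbxb-78 (-1.12 ± 0.14) and fbxb-118 (-0.92 ± 0.11) lower, bath-38 (0.61 ± 0.07) higher. The list median was -0.11 (camera adjusted p = 0.023, and adjusted p = 0.893 with an estimated correlation). Cytosolic ribosomal protein genes were nearly level, with 2 of 81 higher and 3 lower (0 and 3 adjusted over the list alone). The genes rpl-10 (-0.27 ± 0.04), rpl-41.1 (-0.56 ± 0.09) and rps-16 (-0.24 ± 0.05) fell, and rpl-31 (0.26 ± 0.07) and rpl-24.2 (0.25 ± 0.08, named after its value was seen) rose. Their median of 0.09 (camera adjusted p = 0.018, and adjusted p = 0.893 with an estimated correlation) turned to -0.02 with total counts alone, and the list was not called there or without HBR227 A. Higher and lower counts without HBR227 A were 3 and 11 for moulting, 3 and 28 for histone and 3 and 8 for ribosomal protein genes.

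Immune and detoxification families changed in both directions. C-type lectin genes had 23 of 147 higher and 14 lower, also adjusted over the list alone, and a median of 0.05 that turned to -0.05 with total counts alone. Among them were clec-1 (0.81 ± 0.06), clec-172 (1.93 ± 0.20) and clec-61 (1.18 ± 0.12), all higher. Without HBR227 A, 50 lectin genes were higher and 20 lower, and camera with the preset correlation called the list higher (median 0.13, adjusted p = 0.0335). With an estimated correlation, run over all libraries, camera gave adjusted p = 0.893 for lectin genes. Lysozyme and saposin-like genes had 9 of 32 higher and 6 lower (10 and 7 adjusted over the list alone), a mean of 0.02 and a median of -0.01 that turned to 0.00 with DESeq2 size factors. Among them were ilys-5 (1.5 ± 0.24) higher and spp-1 (-0.57 ± 0.08), spp-3 (-0.40 ± 0.06) and spp-13 (-0.86 ± 0.14) lower. Of 44 epidermal antimicrobial peptide genes, 6 fell, among them cnc-2 (-1.56 ± 0.21) and abf-2 (-0.92 ± 0.16), and nlp-33 (0.48 ± 0.10) rose (5 and 1 adjusted over the list alone). HBR227 A lay 0.61 below the other HBR227 libraries in this list, and without it 12 were higher and 11 lower. Among 13 p38 pathway immune genes, lys-2 (0.82 ± 0.16) and K08D8.5 (0.69 ± 0.19) rose and clec-85 (-0.77 ± 0.14) and irg-4 (-1.09 ± 0.24) fell, also adjusted over the list alone. Another gene overlaps 27.7% of the clec-85 exon length on its strand. The p38 list had a mean of 0.02 and a median of -0.01 that turned to 0.00 with upper quartile scaling, and HBR227 A lay 1.04 log2 units below HBR227 B, C and D in it. Without HBR227 A, 6 p38 pathway genes were higher and 3 lower, with a median of 0.20. Of 37 intracellular pathogen response genes, 2 rose and 4 fell, also adjusted over the list alone, with pals-31 (0.66 ± 0.14) higher and pals-36 (-0.74 ± 0.14) and pals-6 (-0.66 ± 0.17) lower. Glutathione transferase genes had 4 of 49 lower and 1 higher, also adjusted over the list alone, with gst-27 (-0.74 ± 0.11) and gst-13 (-0.86 ± 0.18) lower and gst-22 (0.54 ± 0.14) higher. HBR227 A lay 1.03 below the other HBR227 libraries in this list, and without it 11 were higher and 13 lower. UDP-glucuronosyltransferase genes had 9 of 65 higher and 6 lower (9 and 7 adjusted over the list alone), with ugt-53 (-1.17 ± 0.18) lower and ugt-18 (0.64 ± 0.10) higher. Their median turned from 0.01 to -0.09 with total counts alone. Cytochrome P450 genes had 5 of 80 higher and 7 lower (5 and 5 adjusted over the list alone), with cyp-34A9 (-0.62 ± 0.08) lower and cyp-13A5 (0.51 ± 0.08) higher. The P450 median of 0.01, with a mean of -0.01, also turned to -0.09 with total counts alone. Without HBR227 A, 24 P450 genes were higher and 11 lower, and 21 UDP-glucuronosyltransferase genes higher and 9 lower. In the metal response list of 11 genes only mtl-1 passed the test, also adjusted over the list alone, and HBR227 A lay 0.93 below the other HBR227 libraries. Without it 3 metal response genes were higher and 5 lower, 13 lysozyme and saposin-like genes higher and 10 lower, and 4 pathogen response genes higher and 7 lower.

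Several marker lists of tissues and of other stages moved with HBR227 A. Body wall muscle genes had 1 of 26 higher, mlc-2 (0.29 ± 0.05), and 2 lower, the titin gene ttn-1 (-0.83 ± 0.21) and hlh-1 (-0.30 ± 0.09), with 1 and 0 adjusted over the list alone, and a median in HBR227 A 0.50 below HBR227 B, C and D. The list median was -0.13, and 0.02 without HBR227 A. Pharynx muscle genes had ttr-36 (-0.29 ± 0.07) lower of 9, also adjusted over the list alone, and lay 0.75 lower in HBR227 A. Of 21 pharyngeal cuticle abu and pqn genes, pqn-75 (0.71 ± 0.08) rose and pqn-13 (-1.26 ± 0.22), abu-12 (-0.98 ± 0.20) and abu-13 (-0.58 ± 0.12) fell, also adjusted over the list alone. Their median was -0.68 (camera adjusted p = 0.018, and adjusted p = 0.893 with an estimated correlation), -0.35 without HBR227 A, and in HBR227 A it fell by 2.49 log2 units from the other HBR227 libraries. Of 18 intestine genes, gtl-1 (0.43 ± 0.09), ges-1 (0.44 ± 0.10) and ifo-1 (0.53 ± 0.13) rose and asp-1 (-0.54 ± 0.06) fell (5 and 1 adjusted over the list alone). Without HBR227 A, 12 intestine genes were higher and 3 lower, and camera with the preset correlation called the list higher (median 0.35, adjusted p = 0.0022). With an estimated correlation, run over all libraries, camera gave adjusted p = 0.893 for intestine genes. Of 14 epidermis genes, the collagen gene dpy-7 (-0.89 ± 0.22) fell, also adjusted over the list alone. No germline gene passed the edgeR test among 21, or adjusted over the list alone (2 at an unadjusted p under 0.05), although their median was 0.31 (camera adjusted p = 0.018, and adjusted p = 0.893 with an estimated correlation). It was 0.09 without HBR227 A, where 3 genes were higher and 1 lower but the list was not called (adjusted p = 0.357), and HBR227 A stood 1.09 above the other HBR227 libraries. None of the 19 oocyte and eggshell genes was called by edgeR either, over all genes or over the list alone (0 at an unadjusted p under 0.05), and HBR227 A stood 1.28 above the others. The gene cpg-1, named after its values were seen, was at 127 CPM in HBR227 A and at most 33.2 in B, C and D. Without HBR227 A, 3 oocyte and eggshell genes were higher and 2 lower, and cpg-1 was called higher (0.34, adjusted p = 0.0011). S phase genes stood 1.08 higher in HBR227 A, and 1 of 28, psf-2 (-0.51 ± 0.13), was lower over all genes and 0 over the list alone. The S phase median of 0.16 turned to -0.19 without HBR227 A, where camera with the preset correlation called the list lower (adjusted p = 0.0022). Over all libraries the estimated correlation of this list was 0.945 (camera adjusted p = 0.961 with it). Other higher and lower counts without HBR227 A were 2 and 11 for S phase, 4 and 6 for body wall muscle, 1 and 1 for pharynx muscle, 2 and 8 for abu and pqn, 0 and 4 for epidermis, 1 and 1 for vitellogenin and 0 and 1 for sperm genes. Vitellogenin genes had vit-6 (0.96 ± 0.21) higher of 6, also adjusted over the list alone, at 2.64 CPM in HBR227. No called gene was found among 9 sperm genes or 5 ribosomal RNA genes by edgeR, over all genes or over the list alone (0 and 1 at an unadjusted p under 0.05). Ribosomal RNA took 5.26% ± 0.379 of the counts in N2 and 5.05% ± 0.874 in HBR227 (SD, n = 4 each; exact permutation p = 0.743).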

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

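All tests of HBR227 A, and the copy, scaling and left-out tests of the heat shock genes, were chosen only after the results were seen; the tests of handling and of other splits were chosen before the data were examined.

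A value was set apart where its gap to the nearest of its group was most of the group's whole range by Dixon's test, which chance does in about 1 in 20 groups. This held for 45 of 392 groups tested, where 19.6 were expected by chance, and 27 of the 45 were values of HBR227 A. Genes chosen after their values were seen are among these groups, and genes of a library can vary together. The 19.6 is thus only a rough guide. The TMM factor of N2 B was 1.07, with the other N2 libraries at 1.02 to 1.03. HBR227 A had the highest value of its strain, apart from the other 3, in CPM of bath-38 (107), cpg-1 (127), dnj-13 (371), flp-10 (62.3), hsp-12.3 (29.6), hsp-12.6 (33.9), pas-1 (40.7), pdi-1 (170), pqn-75 (110) and rpl-31 (1141). HBR227 A had the lowest value of its strain, apart from the other 3, in CPM of D1086.3 (0.524), F14F9.2 (0.458), abu-12 (2.40), aptf-1 (0.720), cct-8 (123), che-10 (131), clec-54 (3.45), col-106 (4.60), daf-28 (8.12), gst-13 (10.6), hsp-1 (2996), hsp-17 (28.3), ifo-1 (110), ins-3 (10.1), lys-2 (12.1), nlp-33 (31.7) and unc-25 (49.9). HBR227 B had the highest value of its strain, apart from the other 3, in CPM of hpo-18 (40.3). HBR227 B had the lowest value of its strain, apart from the other 3, in CPM of asp-1 (2065), gpd-2 (1281) and ins-24 (8.12). HBR227 D had the highest value of its strain, apart from the other 3, in CPM of nhr-119 (69.7). N2 B had the highest value of its strain, apart from the other 3, in CPM of hpo-18 (64.8), mlt-8 (15.1) and pqn-13 (31.01). N2 B had the lowest value of its strain, apart from the other 3, in CPM of atg-18 (202), flp-3 (78.4), flp-10 (21.03), ida-1 (909), mlc-2 (2398) and sbt-1 (501). N2 C had the highest value of its strain, apart from the other 3, in CPM of clec-172 (0.551) and pals-6 (3.61). N2 D had the lowest value of its strain, apart from the other 3, in CPM of unc-25 (70.8).

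In HBR227 A, 1367 genes were more than 1 log2 unit below the mean of HBR227 B, C and D and 453 more than 1 above it, 346 and 7 by more than 2, with a median of 0.03 over all genes. Its depth was the lowest of its strain but 1.11 times that of N2 A, which did not stand apart, its aptf-1 level of 0.720 CPM was that of the mutant, and exon length explained little (Spearman correlation across genes 0.0283), so none of these 3 accounts for it. The vitellogenin excess of 2.87 CPM, against 634 CPM for oocyte and eggshell genes, speaks against RNA from adults. Dilution by RNA without larval neuronal transcripts would lower neuronal genes together. NLP neuropeptide genes lay 0.015 log2 units above the other HBR227 libraries (at most 0.0944 either way in another library against the rest of its strain). FLP genes lay 0.08 above, and pan-neuronal, sleep signalling and RIS and GABA genes 0.08, 0.12 and 0.22 below. Single genes fell more, as with lim-6 (0.68 below) and unc-25 (0.61 below). Such dilution alone thus does not account for the genes more than 1 log2 unit lower. RNA from unhatched embryos stays open, because the oocyte and eggshell list, 1.28 log2 units higher, was the list that rose most and so does not decide it. The labels give no biological difference between this library and its replicates, so none was weighed.

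Heat shock genes rose in the mutant, a group in the design. Shared reads do not account for it, since 7 of 9 members without a near-identical copy were called, nor does scaling (lowest list median over the other scalings 0.33) or HBR227 A (median without it 0.46). Culture or handling differences between the strains could give the same rise and cannot be told from the genotype here, since the letters do not pair the libraries throughout: 1 of 4 had a correlation of deviations over 0.1 across all genes, and over heat shock genes the values were 0.33, 0.74, 0.78 and -0.40.

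The gene counts were tested over the 35 ways to split the libraries into 4 and 4. The real split was the only 1 with 3774 or more calls, with 1960 or more higher and with 1814 or more lower, and the highest other gave 0. For lists the real split called 16, all 35 splits called as many or more, and the highest other called 34, so the number of called lists may reflect the preset correlation.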

How the results depend on the processing

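Only the correlations over heat shock genes were chosen after the results were seen. Correlations estimated per list ended all 16 list calls and left 0. In the settings with a preset correlation, 17 of 49 lists kept the sign of the median and their side of the threshold throughout, 18 had a median that changed sign somewhere, and 7 lost their call somewhere. Of the 18, 2 were called lists, pan-neuronal genes (-0.01) and cytosolic ribosomal proteins (-0.02), both with total counts alone. S phase genes, not called with all libraries, ran from -0.19 without HBR227 A, where they were called lower, to 0.28 without HBR227 D. Of the named genes 3 changed sign in some setting, unc-25, hsp-17 and stip-1, and none of these was called. Total counts alone gave 1174 genes higher and 3111 lower, an adjusted p under 0.01 gave 1722 genes (952 higher, 770 lower) and 9 lists, and a test against a fold change of 1.5 gave 98 genes (45 higher, 53 lower). Lists were not run with DESeq2 or with the test against a fold change. Leaving out each library in turn gave 2423 to 7906 genes, 1317 to 3748 higher and 1034 to 4158 lower. The highest counts came without HBR227 A, and counts fell by more than 1.5 times without N2 B, HBR227 C or HBR227 D, and for lower genes also without N2 C and N2 D; the cause was not tested. With the replicate letter as a block 3065 genes were called (1639 higher, 1426 lower). The same-letter correlations of deviations were -0.01, 0.14, 0.03 and -0.01, and 2 of 4 N2 libraries correlated best with their own letter; over heat shock genes alone the correlations were 0.33, 0.74, 0.78 and -0.40, so not every letter paired its libraries.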

Other observations

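The gene families and genes in this part, and their tests, were chosen after the results were seen, except for the linked-variant test. Among 150 families of at least 8 genes that share a name, all 8 chaperonin genes cct-1 to cct-8 rose (median log2 fold change 0.44, camera adjusted p = 4.2e-08, and adjusted p = 0.990 with an estimated correlation), from 0.25 ± 0.06 for cct-8 to 0.59 ± 0.05 for cct-4. The J-domain gene dnj-20 rose by 1.2 ± 0.05 and pqn-59, at 5170 CPM in HBR227, by 0.89 ± 0.05. The dnj family as a whole went both ways, with 5 of 29 members higher and 7 lower (median -0.07, camera adjusted p = 0.954). Of 15 nspc genes 12 rose and none fell (median 1.28, adjusted p = 6.9e-06, and adjusted p = 0.990 with an estimated correlation); these are near-identical copies, so single members are uncertain. Of 34 sdz genes 18 fell and 1 rose (median -0.59, adjusted p = 3.1e-06, and adjusted p = 0.990 with an estimated correlation). Mitochondrial ribosomal protein genes had 10 of 29 mrps members lower and 2 higher, and 8 of 42 mrpl members lower and 1 higher. The peptide gene snet-1 fell from 139 to 50.9 CPM (-1.45 ± 0.06) and the asparagine synthetase gene asns-2 from 220 to 90 CPM (-1.29 ± 0.08).

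A hypothesis was that variants linked to aptf-1 on chromosome II cause the large changes. Of 432 called genes with an absolute log2 fold change of at least 1, 4.17% lay within 2 Mb of aptf-1. The share of tested genes was 5.17% (Fisher exact p = 0.380), so no excess near the gene was found. Closeness can show only effects on neighbouring genes, so linked variants that act on distant genes were not tested. Variants elsewhere in the genome of HBR227 cannot be told from the aptf-1 allele in this design either.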
